A study of Clio pyramidata with 8 samples.

How the data were processed

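Messenger RNA was profiled in 8 adult Clio pyramidata, a shelled planktonic sea snail (a thecosome pteropod), taken from its shell and extracted as a whole body. Per the labels' protocols, each animal sat alone in filtered seawater with antibiotics for 9 to 11 h after the water had been bubbled with ambient air (about 380 ppm CO2) or with a gas mixture of 800 ppm CO2. The labels name the reagents of 2 RNA extraction methods and do not say which animal had which, so extraction could not be entered as a batch. Libraries were made with a TruSeq RNA kit by a commercial provider, multiplexed, and read as short paired ends on 2 lanes.

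The deposited table holds FPKM values (fragment counts scaled to transcript length and to the number of mapped fragments), which the authors had normalized by TMM, per the file's own name. Values are rounded to 2 decimals, and 1 column stands for each animal. The submitters' processing notes name Trimmomatic, Bowtie and edgeR without versions or roles. The quantification program, the transcriptome assembly and the rule by which transcripts were listed are not given in the sources used here. The table lists 27393 transcripts by number, the highest number being 45739, and 18346 numbers up to it were not analysed here. No source used here pairs a transcript with a gene name, a sequence, a length or an assembly component. The gene lists and the sums per component that had been planned were therefore not run, and transcripts are reported by identifier only. No genome coordinates apply to this transcriptome. All 8 columns matched 1 sample each, no 2 columns were identical, and 0 columns were left out.

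Animals A to D formed the 800 ppm group and E to H the 380 ppm group (4 animals each), as their titles say. The letters name separate animals and pair nothing. Because FPKM are not counts, no count model was used. The main test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(FPKM + 1), for the 19379 transcripts with a mean of at least 1 FPKM over the 8 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate changes of transcripts near 1 FPKM. Whole profiles were compared by 1 minus Spearman's rho, and values per animal by exact permutation tests over the splits of the 8 animals (scipy 1.17.1, numpy 2.4.6, Python 3.11.15). With 4 animals per group such a test cannot give a two-sided p under 0.0286. With D and E both left out, too few splits remain for any of these tests to give a p under 0.05. With 1 animal left out, the same holds for the two-sided tests of differences between group means. The transcripts to name were fixed in advance as those with the smallest p, 2 in each direction, since identifiers carry no gene names. These choices and the alternatives in the closing section were made before the data were examined, except where it says otherwise.

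The limma step was tested on simulated FPKM drawn with each transcript's own mean and spread, in which 200 transcripts were changed by known folds. At the animals' real spread and among 19049 tested transcripts, it recovered 5 of 50 transcripts changed 4-fold (10%), 34 of 50 changed 16-fold (68%) and 46 of 50 changed 64-fold (92%), with 11 false calls among 142. The simulation drew transcripts independently, whereas in the real libraries many vary together. Its many large changes ease the adjusted threshold for the smaller ones, so recovery may be lower where large changes are few or transcripts are low.

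The table gives no read totals, so absolute depth is unknown. The relative number of fragments per unit of TMM-normalized FPKM was recovered from the steps of low values: where whole fragments were counted, the values of 1 transcript are whole multiples of what 1 fragment is worth in each library. A lattice was fitted to 300 transcripts with values under 1 FPKM and was repeated on 3 draws, which differed by at most 0.00515 on the log2 scale. In a further draw of low transcripts, which was not kept apart from the fitted ones, 90.5% of 1818 values fell within 0.1 of a whole number of fragments. Each transcript's own step was fitted to the values checked, so this share is not an independent check. The highest share with the libraries' fitted steps shuffled and the transcripts' steps fitted in the same way, over 20 shuffles, was 64.9%. The method returned the values put into simulated data. Those values lay on the steps that the fit searches and all simulated fragments were whole, which eased their recovery. None was as large as the fitted log2 worth of 1 fragment relative to G in D (2.00) or E (2.22). The simulation therefore did not test the values of D and E. This number depends on the authors' scaling and on how much of a library a few transcripts take up, so it is not the sequencing depth of a library, and it was used only for descriptions and for tests of low values. Its product with summed FPKM over the listed transcripts gave the fragments of each library scaled to transcript length, relative to G. Fragments were not marked by molecular identifiers, so statements on fragments cover counting error only.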

Results

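The series asked how the transcriptome of the pteropod Clio pyramidata responded to a short exposure to moderately raised CO2. Whole bodies of 4 animals held at 800 ppm CO2 (A to D) and of 4 held at ambient CO2, about 380 ppm (E to H), were sequenced, 1 library per animal, after 9 to 11 h. The animals were separate individuals, so the spread within a group includes both biological and technical variation. Of the 27393 listed transcripts, 2 were listed at 0 in every library.

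The libraries differed widely in how much of their signal sat in a few transcripts and in how many fragments stood behind 1 unit of FPKM. Relative to G, where it was highest, the number of fragments per unit of FPKM recovered from the steps of low values was 52.5% in A, 67.9% in B, 45.8% in C and 25.0% in D at 800 ppm. It was 21.4% in E, 66.4% in F and 49.6% in H at 380 ppm. Multiplied by summed FPKM, which gives the fragments of the listed transcripts scaled to their length, the libraries lay much closer, from 87.4% of G in D to 137% in H, with E at 105%. The mean number of fragments per unit of FPKM was 47.8% ± 17.8 (SD, n = 4) at 800 ppm and 59.4% ± 32.8 (SD, n = 4) at 380 ppm, and no difference was detected (two-sided exact permutation test, p = 0.6). The difference of -11.5 points turned to 2.01 without G and was -3.93 without D, -18.2 without B and -24.2 without E. Zeros made up 27.8% of transcripts in D and 22.0% in E, against 2.57% to 9.15% in the other 6 animals. Transcripts at 1 FPKM or more numbered 16903 ± 2826 (SD, n = 4) at 800 ppm and 16480 ± 1534 (SD, n = 4) at 380 ppm, a difference smaller than the spread between animals (two-sided exact permutation test, p = 0.8). The direction of this difference of 424 depended on single animals and on the limit: it was -120.5 without A, -308 without B, -317 without E and -429 at a limit of 5 FPKM. It grew to 1775 without D, 837 without G, 664 without H and 1034 without both D and E (exact permutation p between 0.171 and 1 over these alternatives). With any animal left out this test cannot give a p under 0.05, so it could not detect a difference there. The lowest numbers were 12851 in D and 14258 in E.

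The transcript of highest mean level, GAWL01040442, singled out after its values were seen, was also the most abundant in each of the 8 libraries. It made up 34.8% ± 21.9 (SD, n = 4) of summed FPKM at 800 ppm and 36.7% ± 18.5 (SD, n = 4) at 380 ppm (two-sided exact permutation test, p = 0.886). This difference of -1.87 points turned to 0.546 without A, 4.91 without B and 5.45 without E, and was -12.2 without D, -9.52 without G and -4.86 without both D and E. Its share ran from 13.7% in G to 65.8% in D. The 10 most abundant transcripts of each library together held 44.6% ± 18.8 (SD, n = 4) of summed FPKM at 800 ppm and 44.0% ± 17.9 (SD, n = 4) at 380 ppm (two-sided exact permutation test, p = 0.943). That difference of 0.592 points turned to -8.36 without D, -6.87 without G and -1.24 without both D and E, and rose to 7.71 without E and 6.30 without B. With any 1 of A, C and F left out it lay between 1.32 and 2.43, and it was 0.207 without H and 1.77 for the 1000 most abundant transcripts. The highest shares were again in D, at 71.4%, and E, at 65.4%.

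**Figure D1:**
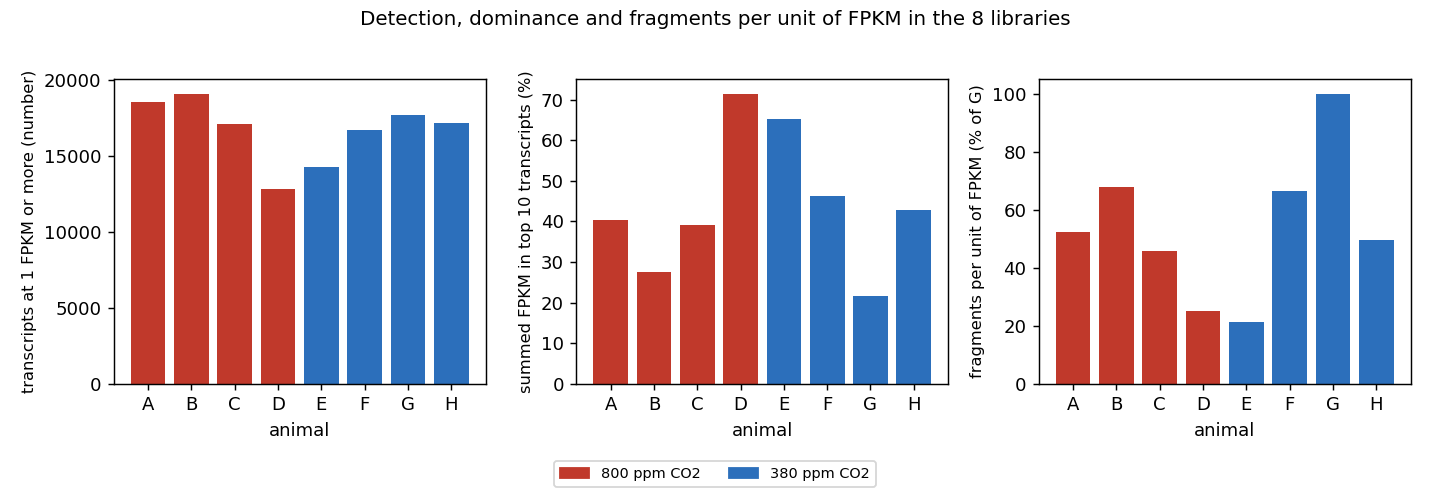
Bars give, for each animal, the number of transcripts at 1 FPKM or more (left), the percentage of summed FPKM in its 10 most abundant transcripts (centre) and its number of fragments per unit of FPKM as a percentage of animal G (right), with red for 800 ppm and blue for 380 ppm CO2. D at 800 ppm and E at 380 ppm have the fewest transcripts (12851 and 14258), the highest shares in 10 transcripts (71.4% and 65.4%) and the fewest fragments per unit of FPKM (25.0% and 21.4% of G).

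No greater resemblance among animals of the same CO2 level than between levels was detected. Over the 19379 tested transcripts, Spearman's rho between animals averaged 0.559 ± 0.153 (SD over 12 pairs) within groups and 0.570 ± 0.143 (SD over 16 pairs) between groups. The mean distance between groups minus that within groups was -0.0119, and 18 of the 35 splits of the 8 animals into 4 and 4 gave a value as large (one-sided exact permutation test, p = 0.514). The sign depended on single animals: the value was 0.00619 without B, 0.00856 without D, 0.00937 without E, 0.00472 without H and 0.0524 without both D and E (exact permutation p between 0.2 and 0.514). Without both D and E this test cannot give a p under 0.05, so it could not detect a separation there. With another animal left out the value stayed below 0, down to -0.0404 without G. Only A and F, 2 of the 8 animals, had their closest match in their own group. The most similar pair was C at 800 ppm with H at 380 ppm (rho = 0.808), and the least similar was D with G (rho = 0.200). The first principal component carried 42.6% of the variance and placed D, at 190, farthest from the rest, with E at 76.1 and F at 58.1 next and the other 5 animals between -94.8 and -27.4. These correlations were computed over transcripts, which are not independent replicates.

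**Figure D2:**
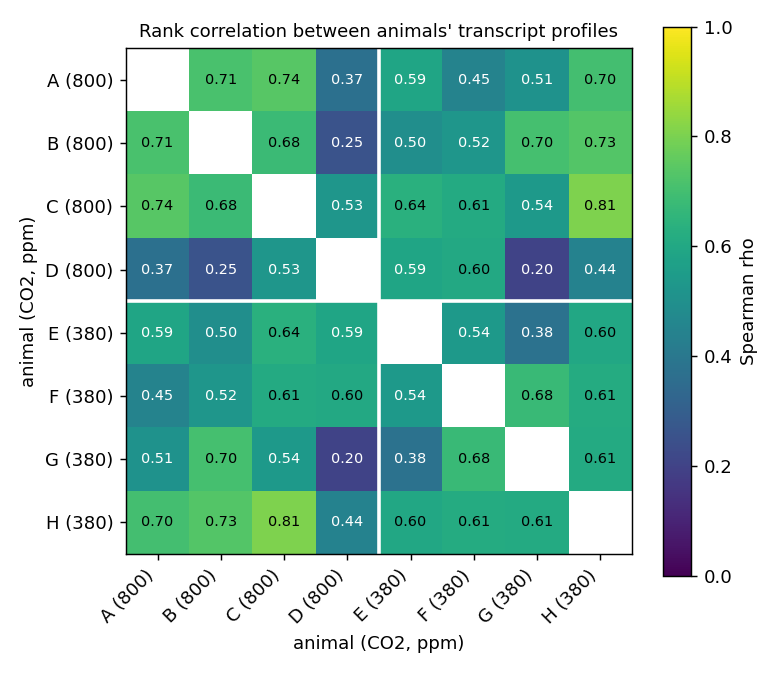
Each square gives Spearman's rho between 2 animals over the 19379 tested transcripts, with animals on both axes and white lines parting the 800 ppm from the 380 ppm group. High and low values stand in all 4 blocks: rho is 0.808 for C with H across groups and 0.200 for D with G.

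The spread among animals was also not distinguishable between the CO2 levels. The mean distance (1 minus rho) was 0.453 among the 800 ppm animals and 0.430 among the 380 ppm animals, a difference of 0.0224 (two-sided exact permutation test, p = 0.971). The median SD of log2(FPKM + 1) per transcript was 0.67 at 800 ppm and 0.83 at 380 ppm, a pair of values that were not tested. The sign of the difference in distance again depended on single animals. It turned without F (-0.0142), without H (-0.0184), without both D and E (-0.0801) and as a Euclidean distance (-0.886), and it was 0.120 without C, 0.0804 without E, 0.0777 without A and 0.0419 without G. Without animal D it turned to -0.140, with a distance of 0.290 among the 3 remaining 800 ppm animals and 0.430 among the 380 ppm animals (exact permutation test, p = 0.2).

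No transcript passed the test for a difference between 800 and 380 ppm CO2. With limma and Benjamini-Hochberg adjustment over 19379 transcripts, 0 were higher and 0 were lower at 800 ppm at an adjusted p of 0.05, and the smallest adjusted p was 0.997. At an unadjusted p under 0.05 there were 845 transcripts (4.36%), 328 with higher and 517 with lower values at 800 ppm, where chance alone gives 969. The groups did not overlap in 697 transcripts (3.60%), of which 191 had the higher values at 800 ppm and 506 the lower, against 554 (2.86%) given by chance. The median log2 change over all tested transcripts was -0.10, and 1197 transcripts had an estimated log2 change above 1 and 1019 one below -1. The median 95% confidence interval reached 1.26 to each side on the scale of log2(FPKM + 1), a factor of 2.40 in FPKM + 1. For 12480 transcripts (64.4%) the interval lay within a 4-fold change of FPKM + 1 either way, and for 411 within a 2-fold change. In low transcripts this scale narrows the interval, so it does not bound the change in FPKM itself. Of the tested transcripts, 8331 had a mean of at least 5 FPKM. In simulated data with the animals' spread, the same adjusted test recovered 10% of 4-fold and 68% of 16-fold changes of FPKM + 1. The lowest transcripts were not changed there, and many larger changes eased the threshold, so recovery in the real data may be lower. Leaving out D and E, an alternative chosen after seeing the data, gave 0 transcripts past the adjusted threshold and 1727 at an unadjusted p under 0.05. That unadjusted count was 441 without A, 496 without F, 511 without G and 1660 without E. The balance of directions turned without D, to 835 with higher and 349 with lower values.

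**Figure D3:**
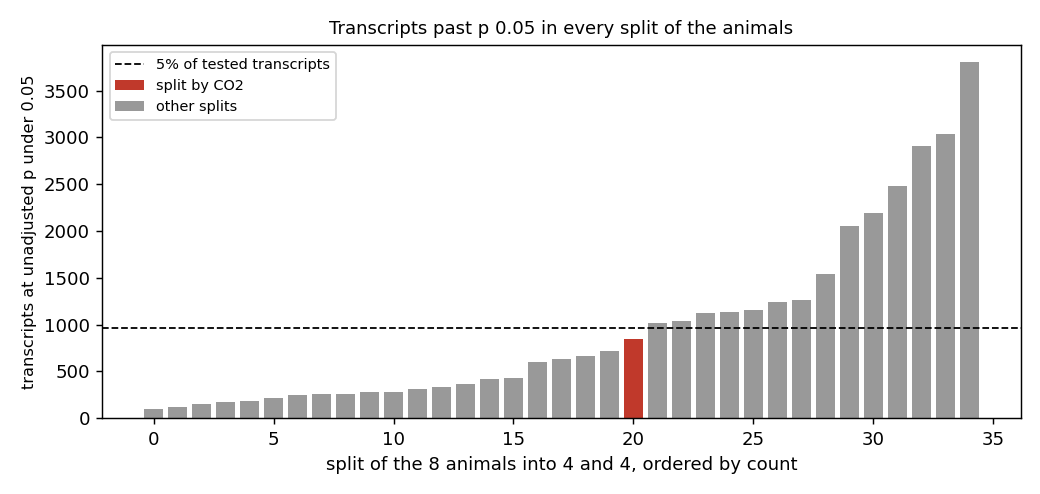
Bars count transcripts at an unadjusted limma p under 0.05 for each of the 35 splits of the 8 animals into 4 and 4, in ascending order, with the split by CO2 in red, other splits in grey and 5% of the tested transcripts as a dashed line. The split by CO2 gives 845 transcripts, below the 969 of the dashed line, and the highest other split gives 3802.

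The transcripts with the smallest p in each direction had groups that did not overlap, and they too did not pass. Among those with higher values at 800 ppm, GAWL01034576 stood at 9.11 ± 3.08 FPKM (SD, n = 4) at 800 ppm and 1.42 ± 0.68 FPKM (SD, n = 4) at 380 ppm. Its log2 change was 2.06 with an SE of 0.42, and its limma adjusted p was 0.997. GAWL01020865 stood at 8.98 ± 3.34 FPKM (SD, n = 4) at 800 ppm and 1.43 ± 0.84 FPKM (SD, n = 4) at 380 ppm, a log2 change of 2.06 with an SE of 0.45. Among those with lower values at 800 ppm, GAWL01009441 stood at 1.46 ± 0.32 FPKM (SD, n = 4) at 800 ppm and 10.3 ± 3.17 FPKM (SD, n = 4) at 380 ppm. Its log2 change was -2.16 with an SE of 0.39. GAWL01022313 stood at 1.31 ± 0.83 FPKM (SD, n = 4) at 800 ppm and 11.1 ± 4.68 FPKM (SD, n = 4) at 380 ppm, a log2 change of -2.38 with an SE of 0.46. The limma adjusted p was 0.997 for each of the 4. All 4 had a mean over the 8 libraries of at least 5 FPKM, as did 8331 transcripts in all, but each stood near 1 FPKM in its lower group. Their gene identities are not given in the sources used here.

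**Figure D4:**
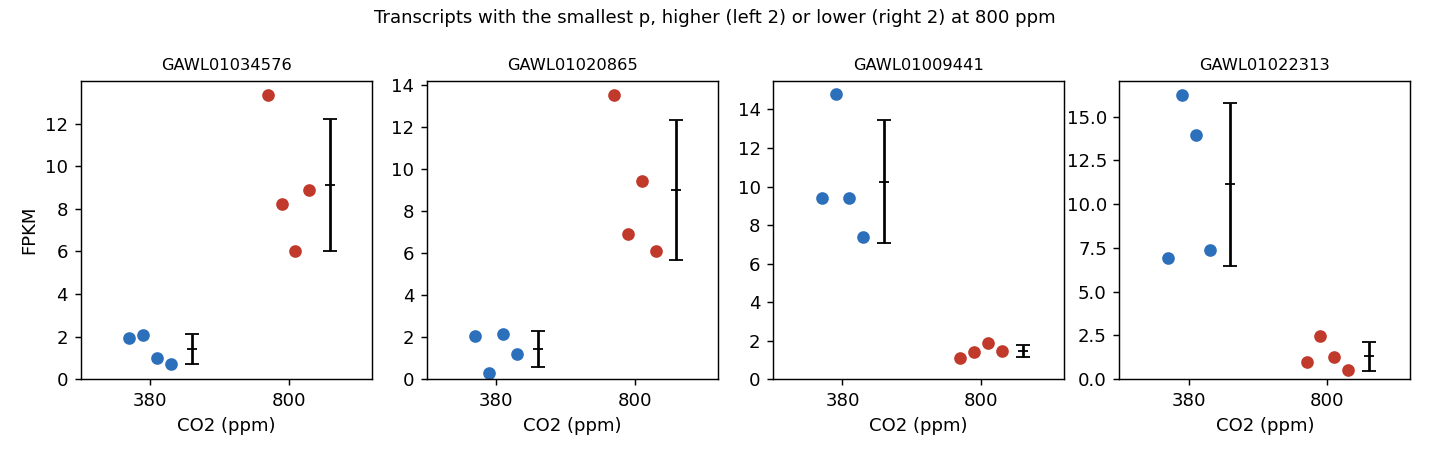
Points give the FPKM of each animal at 380 ppm (blue) and 800 ppm (red) CO2 for 4 transcripts, with the black bar marking the mean and SD of the 4 animals of a group. In each panel the groups do not overlap, as for 697 of the 19379 tested transcripts, and none of the 4 passes the adjusted threshold (limma adjusted p = 0.997).

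Transcripts switched on or off with CO2 were not found under the definition fixed in advance. A transcript counted as such at 1 FPKM or more in all 4 animals of one group and under 0.1 FPKM in all 4 of the other, and 0 transcripts met this in either direction. No tool or p-value enters this count. With off set at under 0.5 FPKM, 1 transcript was on at 800 ppm alone and 1 at 380 ppm alone. Without D and E, 4 transcripts were on in the 3 remaining animals at 800 ppm and off in the 3 at 380 ppm, and 0 the other way.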

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

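The count of transcripts at an adjusted p of 0.05 was 0 in all 22 alternatives, which covered pseudocounts, filters, scalings, thresholds, limma's variance options and array weights, each animal left out in turn, and D and E left out together. The last was the only one of them chosen after seeing the data. Over the 20 refits the smallest adjusted p ranged from 0.239 (without D) to 0.99998. The count at an unadjusted p under 0.05, 845, became 251 with a minimum mean of 5 FPKM, which tests fewer transcripts, 1415 with array weights and 1727 without D and E, and ranged from 441 to 1660 with 1 animal left out. Counts of 441 without A, 496 without F, 511 without G and 1660 without E lay over 1.5 times from the full count; the cause was not tested. The 4 named transcripts kept their direction in all 20 refits, with log2 changes of 1.10 to 2.76 for those with higher and -3.08 to -1.22 for those with lower values, and adjusted p from 0.552 to 0.99998. Because their groups do not overlap, only the alternative scalings could have turned that direction, so its being kept is no support. The other tested differences each changed sign with at least 1 choice, with exact p between 0.171 and 1 over their 69 alternatives. With any animal left out, the two-sided tests of group means could not give a p under 0.05. These were the tests of detected transcripts, of shares and of fragments per unit of FPKM, which could not detect a difference there. Separation by CO2 (-0.0119) was 0.0524 without D and E and ranged from -0.0404 to 0.00937 with 1 animal left out. The difference in spread (0.0224) was -0.886 as a Euclidean distance and -0.0801 without D and E, and ranged from -0.140 to 0.120. The difference in detected transcripts (424) was -429 at a limit of 5 FPKM and ranged from -317 to 1775. The difference in the share of the top 10 transcripts (0.592 percentage points) was -1.24 without D and E and ranged from -8.36 to 7.71. With animals left out after seeing the data, the difference in fragments per unit of FPKM (-11.5 points, as a percentage of G) ranged from -24.2 to 2.01, and that in the share of the most abundant transcript (-1.87 points) from -12.2 to 5.45. The on-off count, 0, became 2 with off under 0.5 FPKM and 4 without D and E, where fewer animals had to meet the definition. No value could be given for sums per component or for gene lists, since the identifiers show neither. The number of fragments limits the low transcripts most: 1 fragment was worth a median of 0.269 FPKM in E and 0.0575 FPKM in G.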

Other observations

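Of the tests in this part, those on fragments per transcript in D and E, on correlation among the transcripts low in D, on fragments per unit of FPKM for the transcripts high in 1 animal and on carry-over had their outcomes specified before their values were seen; the others, and the use of the spread between animals to read the zeros and fragments of D and E, were chosen after the results were seen.

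A large block of abundant transcripts was almost missing from animal D and varied widely among the others. In D, 326 transcripts lay at least 8-fold below the next lowest animal on the scale of FPKM + 1, while such transcripts numbered 6 in E, 1 in B and 0 in each of the other 5. The 326 made up 33.9% of summed FPKM in B, 28.5% in A, 23.1% in G, 15.0% in C, 11.3% in H, 2.83% in E, 2.75% in F and 0.0303% in D. The most abundant of them, GAWL01022954, stood at 23459 FPKM in A, 20598 in B, 11239 in C, 38.0 in D, 6294 in E, 1307 in F, 7075 in G and 11456 in H. The block's share was low in D at raised CO2 and in E and F at ambient CO2. A share also depends on the rest of the library, and summed FPKM was 2202525 in E and 706004 in F. The median FPKM of the members was 40.5 in E, 21.2 in F and 0.435 in D. Its members were selected as lowest in D, so they could not be higher in all animals at raised CO2. This selection therefore cannot show whether the block follows CO2. Without D, its share was 28.5%, 33.9% and 15.0% at raised CO2 (A, B and C). At ambient CO2 it was 2.83%, 2.75%, 23.1% and 11.3% (E, F, G and H). These ranges overlap, since G lay above C, and the difference was not tested. In FPKM, the median over all 326 members overlapped too, at 96.6 in C, 105 in H and 118 in G. Over the 38 members at 100 FPKM or more in every animal but D, the median did not overlap. It was 2798, 2771 and 1558 FPKM in A, B and C, and 559, 202, 1308 and 1487 FPKM in E, F, G and H. These medians were not tested either.

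Too few fragments per unit of FPKM as the whole cause of the block's loss in D is argued against. E, which had fewer than D (21.4% of G, against 25.0%), had 6 transcripts low in it alone where D had 326. At the largest worth of 1 fragment found among low transcripts, 100 FPKM in D is 58.2 fragments, and 38 members stood at 100 FPKM or more in every other animal. The lengths of the members are unknown, so this worth is a guide and no bound for them. Over the 7 animals other than D, the members rose and fell together: the median pairwise correlation was 0.856, against a 95th percentile of 0.151 over 1000 random sets matched on level. The random sets were not matched on how widely transcripts varied among animals, so the contrast does not by itself point to a single source. A candidate explanation is one shared source, such as a tissue or gland or a body state that was present to different degrees in the animals or was lost with the shell in D. Which source it is stays open, because the transcripts have no gene names here, and the extraction method of each animal, which the labels do not give, is a further open explanation.

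D had more zeros than its low number of fragments per unit of FPKM accounts for, and for E this is unsettled. When the other 6 libraries were thinned to the number in D, D still had 22.6 percentage points more zeros among low transcripts than the highest of them, beyond the SD of 10.7 points between the 6, which argues against it as the whole cause. E had 12.5 points more in the same test (SD 10.8), but 8.86 points (SD 11.4) with no upper limit on its own values, which is within the spread between animals. If few distinct molecules had been sequenced, the mean number of fragments per low transcript would match the thinned libraries while fewer transcripts hold them. That mean, with counts above 10 set to 10, was 0.351 to 0.874 times those of the thinned libraries in D and 0.497 to 1.1999 times in E; lying below all 6 was set beforehand as evidence against low complexity, but this bound left out the spread between animals, and the highest ratio in D lies within it (-0.19 on the log2 scale, SD between the 6 0.57), so low complexity and lower true levels of these transcripts stay open in both.

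Small sets of transcripts were high in a single animal. With a gap of at least 64-fold on FPKM + 1 to the next animal, there were 6 such transcripts in C, 4 in E and 1 in B. The 6 in C stood at 89.98 to 705 FPKM there and at no more than 0.39 FPKM in any other animal. The highest in E, GAWL01006673, stood at 33696 FPKM in E and at no more than 6.32 FPKM elsewhere. Among low transcripts 3 fragments were worth at most 6.01 FPKM in any library, but these transcripts' lengths may differ from those of the 11, so this is no bound for them. Too few fragments in the other libraries is argued against for all but GAWL01042601, which stood at 0 in the other 7 animals. The rest had values above 0 elsewhere, and where whole fragments were counted such a value, at most 6.32 FPKM, is worth at least 1 fragment. RNA of another organism, such as a parasite, a virus or food, is a possible explanation for the 6 in C, and it cannot be told apart from expression by the animal without sequences, which were not used here. The low values of the 11 transcripts in the other animals could be carry-over between multiplexed libraries, but they did not clearly follow the level in the 1 animal (across transcripts, Spearman's rho = 0.291, permutation p = 0.384, Pearson's r on log10 values = 0.593, and rho = -0.183 without the 2 transcripts farthest from the median level), which leaves this open.

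Chance could not be excluded for the counts above 0 in the CO2 comparison. For the unadjusted count of 845, 15 of 35 splits gave as many, and the highest other was 3802 (A, B, G and H against the rest). For the 697 transcripts without overlap, 10 of 35 gave as many and the highest other was 2149, in that same split. The counts of 0, of transcripts past the adjusted threshold and of on-off transcripts, cannot be tested this way, since all 35 splits reach 0 by construction. The highest other split for both was A, B, C and H against D, E, F and G, with 234 transcripts past the adjusted threshold and 9 on-off transcripts. So many calls where CO2 gave 0 may reflect a structure among the animals that CO2 does not describe, but this split was picked as the highest of 35, and whether chance gives as large a maximum was not tested. GAWL01005480, singled out among the abundant transcripts because its values part the animals this way, stood at 4719 FPKM in A, 2912 in B, 4058 in C and 15145 in H, and at 6.71 in D, 65.85 in E, 3.33 in F and 5.31 in G.

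A small share of transcripts with neighbouring numbers may be pieces or forms of one gene. Among 11230 pairs whose numbers differ by 1, 5.49% had a correlation over 0.9 across the 8 animals (median over all such pairs 0.176), against 1.25% to 1.71% at each distance from 50 to 100. No sequence or gene identity was used here to show that such pairs share a gene, so this stays a hypothesis.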
